A study of Canis lupus familiaris with 29 samples.

How the data were processed

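The data are a single expression table of RNA sequencing libraries from canine lymphomas, together with the labels of 29 samples. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy Mini kit, and libraries were made with Illumina TruSeq kits. Per the series' design text they were sequenced on a HiSeq 2000. Per the submitters' processing notes, FastQC 0.11.2, TopHat 1.4.1 and Cuffdiff were used with the genome build CanFam3.1. The roles, options and order of these tools, the gene annotation release and any scaling between libraries are not given in the sources used here. The deposited values are FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library) per Ensembl gene, made by the authors, and no fragment counts or library totals were used. FPKM divides each gene by its length and by the library's total, so a rise in a few abundant genes lowers the value of all others, and any scaling between libraries moves all genes of a library together.

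The table holds 78 columns of values. The 29 columns whose names are the titles of samples were used, and 49 columns that match no sample title were not used. Phenotype, sex, neuter status and age were taken from each sample's labels, and libraries were numbered within a phenotype in accession order, which pairs no libraries. Phenotype is written with a hyphen in the labels of 8 B-cell and 2 T-cell samples and with a space in the others. No sequencing batch is given in the labels, and this spelling was tried as a possible one. The numbers in the sample titles, whose meaning the labels do not give, were not used as a batch. No 2 libraries held the same values, and the highest correlation between 2 libraries was 0.9776.

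The table names genes only by Ensembl ID. Of its 16382 IDs 0 could be matched to a symbol, because the gene table at hand lists no Ensembl IDs. The 24 gene lists fixed before the data were examined could therefore not be tested, nor could the marker genes of each phenotype be read as a check of the labels. Enrichment, gene positions, GC content and gene length were not analysed here. The rule for named genes, fixed at the same time, took the 8 genes with the largest log2 change in each direction that were past the threshold, carried a symbol and had a mean of at least 1 FPKM. It names none without symbols, so after the data were examined the 2 IDs with the largest change in each direction were taken by the same rule without the symbol, and the 1 ID past the threshold for sex was added.

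Values were tested as log2(FPKM + 1), with a pseudocount of 1, which understates the change of genes with low FPKM. Genes with at least 1 FPKM in at least 5 of the 29 libraries were kept, which left 11552. Models were fitted with limma 3.58.1 in R 4.3.3 with a variance trend and robust moderation, testing both directions, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. T-cell and B-cell tumours were compared without covariates. Sex and neuter status were tested together with phenotype in the model, age was tested with all 3, and an interaction term of phenotype and sex was tested with neuter status in the model. The variance share of a term is the sum of squares it explains over all genes divided by the total, given the other terms. Single values were compared between phenotypes with exact permutation tests of both directions over all 10015005 choices of 9 of the 29 libraries. The p-values of these tests were not adjusted for the number of values compared. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for these and for the plots.

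Relative depth was read from FPKM below 0.2. Where 2 libraries hold 1 fragment of a gene each, the ratio of their FPKM is the inverse ratio of their depths for every gene, so the most frequent ratio between 2 libraries gives their relative depth. Steps that came out even throughout or midway between whole fragments were used to settle factors of 2. The ratio lay within 0.05 log2 units of the fitted one in 99.88% of 812 ordered pairs of libraries, with a median of 492 genes per pair. This depth includes any scaling between libraries that the authors applied. The method recovered the depths of 29 simulated libraries with a largest error of 0.0 log2 units. Those libraries held whole fragments, gene lengths and expression levels shared by all, and no scaling, so the ratio was exact by construction. This result does not show how accurately the depths of the real libraries were read.

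The tests were tried on simulated data with the real design over 11552 genes, with 100 genes changed 2-fold and 100 changed 1.41-fold. Each gene had the mean of the B-cell libraries and the same spread in both phenotypes. Genes were drawn independently of each other, so the shares and false calls below need not hold for the real libraries, where genes can be correlated. For T-cell against B-cell tumours, 79% of the 2-fold and 22% of the 1.41-fold changes were recovered, with 0 false calls. For sex the shares were 76% and 29% with 4 false calls, for neuter status 67% and 18% with 4 false calls, and for the interaction 23% and 0% with 2 false calls. For a change over 5 years of age they were 84% and 28% with 2 false calls. The alternatives were another pseudocount, no filter and a stricter filter, median-of-ratios scaling, quantile normalization, array weights, plain moderation, other covariates, subsets of dogs, a stricter threshold and each library left out in turn. The others were added after the data were examined: leaving out T-cell libraries 5 and 6, relative depth as a covariate, and the libraries whose label has a space.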

Results

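Gene expression was measured by RNA sequencing in 29 lymphomas of golden retrievers, of which the labels call 20 B-cell and 9 T-cell tumours. How the phenotype of a tumour was determined is not given in the sources used here. The B-cell group held 9 females and 11 males, and the T-cell group held 6 females and 3 males. Of the 29 dogs 23 were neutered, and 3 of the 6 intact dogs were in each phenotype. Age at diagnosis ran from 2.0 to 14.0 years and averaged 7.70 ± 3.08 years (SD, n = 20) for B-cell and 8.81 ± 2.22 years (SD, n = 9) for T-cell tumours, a difference within the spread between dogs (exact permutation test, p = 0.342). The labels do not state that each library came from a different dog, so the p-values measure the spread between these libraries.

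The expression table gave FPKM for 16382 Ensembl gene IDs, of which 1268 were listed at 0 in all 29 libraries. The summed FPKM per library ran from 319067 in T-cell library 5 to 677096 in B-cell library 5. FPKM does not carry the number of fragments, but the smallest steps of the low values gave the depth of each library relative to B-cell library 1. Relative depth ran from 0.522 in T-cell library 5 to 2.21 in B-cell library 8, a 4.24-fold range. It averaged 1.24 ± 0.363 (SD, n = 9) in T-cell and 1.45 ± 0.360 (SD, n = 20) in B-cell libraries, and the difference was within the spread between libraries (exact permutation test, p = 0.165). The absolute depth is unknown, so values carry no counting intervals. The table and the sources used here pair no gene ID with a gene symbol or a position, and genes are therefore described as groups, with 5 IDs given individually, chosen after the data were examined.

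The first question was whether the transcriptome follows the phenotype on the label. It did so in every library. Each of the 29 libraries correlated better with the mean profile of its own phenotype than with that of the other when it was left out of the means, and for each of the 29 the best-correlated other library was of the same phenotype. The margin was smallest for T-cell library 6, at 0.0081 in Pearson r, and for B-cell library 13, at 0.0128. Phenotype accounted for 24.5% of the variance of log2(FPKM + 1) over the 11552 genes tested. Of all 10015005 ways to choose 9 of the 29 libraries, 1 gave as much, the real one (exact permutation test, p = 1e-07, the smallest these choices can give). These checks were added after the data were examined.

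**Figure D1:**
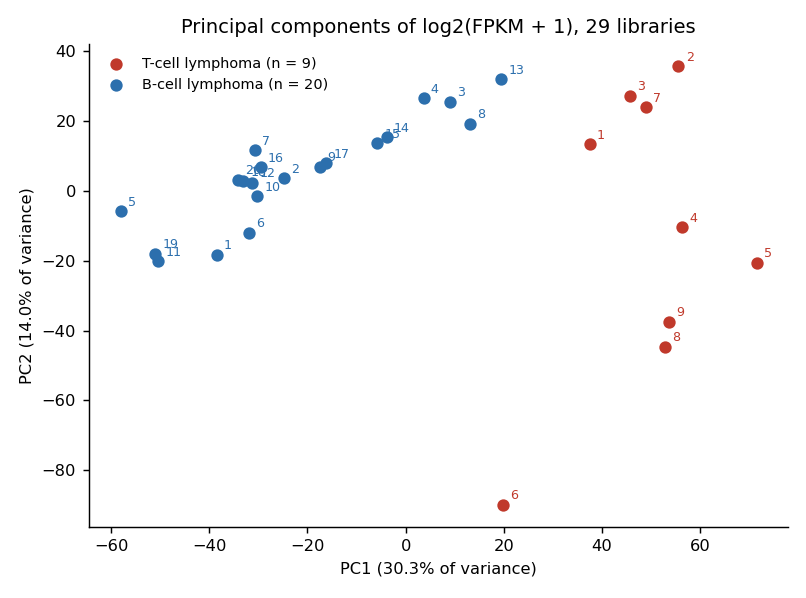
Principal components 1 and 2 of log2(FPKM + 1) over 11552 genes (axes in component units, with the share of variance in percent). Each point is 1 library, numbered within its phenotype; the 9 T-cell libraries lie to the right, from 19.9 to 71.5 on component 1, and the 20 B-cell libraries from -58.1 to 19.4. T-cell library 6 lies apart on component 2, at -89.9.

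The main comparison asked which genes differ between T-cell and B-cell lymphoma. Of 11552 genes tested, 4664 differed (40.4%; limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). As deposited, 2729 genes were higher in T-cell tumours and 1935 were higher in B-cell tumours. That split depended on the scaling between libraries: quantile normalization gave 2120 higher in T-cell and 2540 higher in B-cell tumours, and median-of-ratios scaling gave 2248 and 2345. Most called genes changed modestly, with 73.6% under 2-fold, and the median log2 change of the called genes was 0.74 for those higher in T-cell and -0.66 for those higher in B-cell tumours. The median log2 change of all tested genes was 0.09 as deposited and -0.02 with quantile normalization.

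Genes with larger differences were more often the higher ones in T-cell tumours. Among genes past the threshold, 813 were at least 2-fold higher in T-cell tumours and 418 at least 2-fold higher in B-cell tumours. The T-cell side was also the larger with both other scalings, at 721 against 514 with median-of-ratios scaling and 636 against 517 with quantile normalization. Of the genes at least 8-fold different, 41 were higher in T-cell and 10 in B-cell tumours. For 118 genes the lowest T-cell library lay above the highest B-cell library, and for 65 genes every T-cell library lay below every B-cell library. Chance gives such a separation in 2.0e-05% of genes. The T-cell side was not the larger of these under every scaling, at 94 and 88 with median-of-ratios scaling and at 92 and 94 with quantile normalization. No gene was at 1 FPKM or more in all libraries of one phenotype and under 1 FPKM in all libraries of the other. Fewer libraries leave more genes separated, but the rise was largest for 1 library. Without T-cell library 6 alone the separated genes numbered 196 and 108. Without any other single T-cell library they numbered 120 to 138 and 68 to 88.

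The 2 gene sets took different shares of all FPKM. The 813 genes higher in T-cell tumours took 7.52% ± 1.155 (SD, n = 9) of the FPKM of a T-cell library and 1.99% ± 0.653 (SD, n = 20) of that of a B-cell library. The 418 genes higher in B-cell tumours took 13.6% ± 1.84 (SD, n = 20) of a B-cell library and 6.41% ± 1.89 (SD, n = 9) of a T-cell library. Both sets were chosen on these libraries, so these shares describe the sets and are not independent evidence of their direction. The 10 genes with the highest FPKM in a library took 7.34% ± 2.24 (SD, n = 9) of T-cell and 8.68% ± 1.22 (SD, n = 20) of B-cell libraries (exact permutation test, p = 0.044, not adjusted). The ranges overlapped, from 3.39% to 9.64% in T-cell and from 5.85% to 10.61% in B-cell libraries. The same test gave p = 0.166 for the summed FPKM and p = 0.683 for the number of genes at 0.

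The IDs with the largest log2 changes towards T-cell tumours, in the values as deposited, were ENSCAFG00000007379 and ENSCAFG00000000990. Their order was not fixed: with quantile normalization the log2 change was 4.57 for ENSCAFG00000007379 and 4.63 for ENSCAFG00000000990. ENSCAFG00000007379 stood at 77.2 ± 35.4 FPKM (SD, n = 9) against 2.54 ± 2.54 FPKM (SD, n = 20), a log2 change of 4.63 ± 0.33 (SE; limma adjusted p = 3.47e-11). Its lowest T-cell library, at 37.1 FPKM, lay above its highest B-cell library, at 8.49 FPKM. ENSCAFG00000000990 stood at 266 ± 167 FPKM against 10.999 ± 12.4 FPKM (SD, n = 9 and n = 20), with a log2 change of 4.47 ± 0.63 (SE; limma adjusted p = 2.26e-06). It was above every B-cell library in 8 of 9 T-cell libraries, where it ran from 127.4 to 506.1 FPKM, but stood at 2.85 FPKM in T-cell library 6.

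Towards B-cell tumours the IDs taken in the same way were ENSCAFG00000014130 and ENSCAFG00000014395. ENSCAFG00000014130 stood at 293 ± 141 FPKM (SD, n = 20) against 29.9 ± 38.3 FPKM (SD, n = 9), a log2 change of -4.51 ± 0.60 (SE; limma adjusted p = 1.14e-06). It lay below the lowest B-cell library, at 49.8 FPKM, in 7 of 9 T-cell libraries and was listed at 0 in T-cell library 6. With limma array weights its log2 change was -2.79, smaller in size than the -3.26 of ENSCAFG00000014395. ENSCAFG00000014395 had a log2 change of -3.73 ± 1.0495 (SE; limma adjusted p = 0.0056) with a wide spread, from 3.18 to 2024 FPKM over B-cell and from 0.602 to 71.8 FPKM over T-cell libraries. Only 2 of 9 T-cell libraries lay below all B-cell libraries for this gene.

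**Figure D2:**
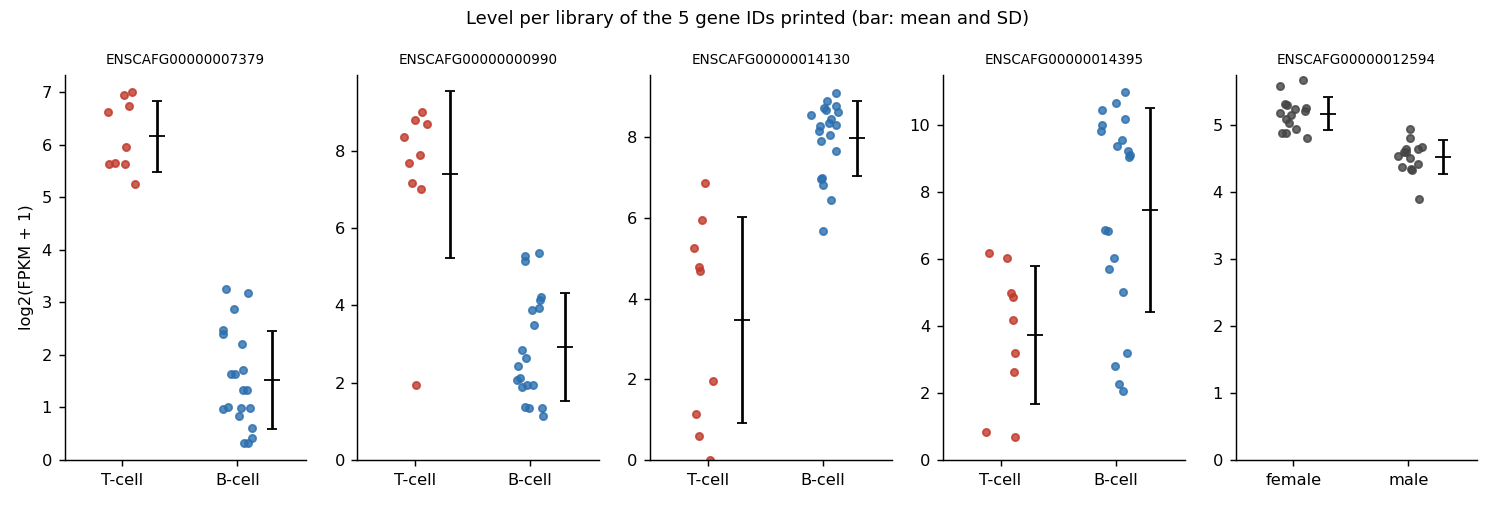
Level of the 5 gene IDs given in the text, as log2(FPKM + 1), with 1 point per library; the bar beside each group is the mean and SD. The first 4 panels compare T-cell (n = 9) with B-cell (n = 20) libraries and the last compares females (n = 15) with males (n = 14); ENSCAFG00000007379 shows no overlap between the phenotypes, while ENSCAFG00000014395 overlaps widely.

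T-cell tumours differed more among themselves than B-cell tumours did. Pairs of T-cell libraries correlated at a median Pearson r of 0.863 (36 pairs, from 0.714 to 0.968), against 0.939 for pairs of B-cell libraries (190 pairs, from 0.829 to 0.978) and 0.851 across phenotypes (180 pairs, from 0.658 to 0.941). The root mean square distance of a library from the mean of the other libraries of its phenotype, scaled for group size, was 0.668 ± 0.206 log2 units (SD, n = 9) in T-cell and 0.511 ± 0.125 (SD, n = 20) in B-cell tumours (permutation test with the distances kept fixed, p = 0.014, not adjusted, added after the data were examined). Each distance depends on the other libraries of its phenotype and was not computed anew for each choice of libraries. This p-value is therefore not an exact test of the spread. The SD per gene averaged 0.592 in T-cell and 0.458 in B-cell tumours, a ratio of 1.29, and was the larger in T-cell tumours for 70.0% of genes. The ratio was 1.14 without T-cell library 6 and 0.997 without T-cell libraries 5 and 6, the 2 T-cell libraries farthest from the T-cell mean, whose removal lowers it by construction.

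**Figure D3:**
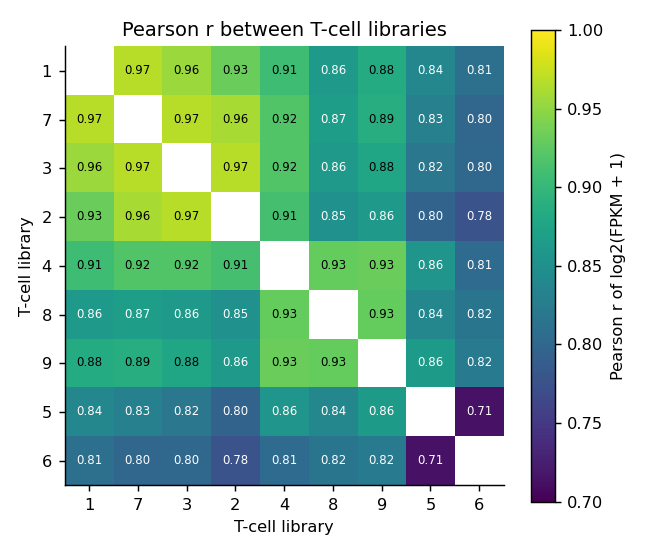
Pearson r of log2(FPKM + 1) over 11552 genes between each pair of the 9 T-cell libraries (colour scale and printed values; both axes list library numbers). Libraries 1, 2, 3 and 7 correlate at 0.931 to 0.968 with each other, libraries 4, 8 and 9 at 0.929 to 0.932, and library 5 reaches at most 0.863 and library 6 at most 0.823 with any other.

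The sex of the dogs was compared with phenotype and neuter status in the model. A single gene, ENSCAFG00000012594, differed (chosen for the text after its values were seen), and it was higher in females, at 35.5 ± 6.52 FPKM (SD, n = 15) against 22.4 ± 3.87 FPKM in males (SD, n = 14). Its log2 change was 0.63 ± 0.10 (SE; limma adjusted p = 0.0101), 11 of 15 females lay above every male and 12 of 14 males lay below every female. At an unadjusted p under 0.05, limma gave 1263 genes, where chance gives 577.6 of 11552, with 671 higher in females and 592 higher in males. Sex accounted for 3.79% of the variance over genes beyond phenotype and neuter status (permutation test within phenotype, 100000 permutations, p = 0.105, added after the data were examined). Within the 20 B-cell dogs alone the gene's log2 change was 0.53 and did not pass (limma adjusted p = 0.384), while the other 11 alternatives gave 0.00233 to 0.0205.

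Neither neuter status nor age had a gene past the threshold. For neutered against intact dogs limma called 0 genes, with 1276 at an unadjusted p under 0.05, and the lowest adjusted p was 0.335. Neuter status accounted for 4.04% of the variance beyond phenotype and sex (exact permutation test over 95760 arrangements within phenotype, p = 0.134). For age limma called 0 genes, with 580 at an unadjusted p under 0.05, close to the 577.6 that chance gives, and age accounted for 2.60% of the variance (permutation test within phenotype, p = 0.378). These variance tests were also added after the data were examined. The 95% interval of a gene's log2 change, not adjusted over genes, reached a median of 0.41 to either side for neuter status and 0.06 per year of age. Changes of this size or smaller were for most genes not detectable with these libraries, and larger ones could also be missed. In the simulated data 67% of 2-fold and 18% of 1.41-fold changes with neuter status passed the adjusted threshold. For a change over 5 years of age these shares were 84% and 28%.

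Whether the difference between T-cell and B-cell tumours depends on the sex of the dog was tested with an interaction term. No gene passed, with a lowest limma adjusted p of 0.188 and 1025 genes at an unadjusted p under 0.05. The 95% interval of the interaction reached a median of 0.73 log2 units to either side. Without T-cell library 7, which leaves 2 of the 3 males with T-cell tumours, 327 genes passed.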

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

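The number of genes that differed between T-cell and B-cell tumours (4664) stayed within 1.5 times that value in 13 of 14 alternatives, from 3122 in the libraries whose label has a space to 6644 with limma array weights. An adjusted p under 0.01 left 3022 genes, 1768 higher in T-cell and 1254 higher in B-cell tumours, as a stricter threshold must leave fewer. The libraries whose label has a space, with fewer samples, gave 1761 genes higher in T-cell tumours against 2729. Leaving out each library in turn gave 4302 to 5025 genes, the extremes without T-cell libraries 7 and 6. Libraries 5 and 6 of the T-cell group, relative depth and the label with a space were chosen after the data were examined. Genes separated without overlap, 118 and 65, were 303 and 181 in neutered dogs and 223 and 134 without T-cell libraries 5 and 6. They were 217 and 158 where the label has a space, and there the SD ratio was 1.49. Fewer libraries leave more genes separated. The neutered dogs and the setting without libraries 5 and 6 also leave out T-cell library 6, without which alone the counts were 196 and 108. Without T-cell libraries 5 and 6, 4653 genes differed. The direction of the 4 IDs held in all 14 alternatives, each with an adjusted p of at most 0.0331. For sex, 2 genes passed with a mean FPKM of at least 5, with quantile normalization and with array weights, and 0 in B-cell dogs only, with fewer samples; each library left out gave 1 to 2, with 2 genes without B-cell library 2, 4, 8, 11 or 13 or T-cell library 7 or 8. ENSCAFG00000012594 passed in 11 of 12 alternatives, the exception being B-cell dogs only (adjusted p = 0.384). Neuter status and age gave 0 genes in all 11 alternatives and with each library left out. The interaction gave 0 genes in all 11 alternatives, and 0 to 327 with each library left out; only the fit without T-cell library 7 gave any, and the cause was not tested. Where the cause of a change is not stated here, it was not tested. The 24 gene lists and genes named by symbol, planned with the same alternatives, were not run for lack of symbols. Unknown fragment counts limit what can be said of genes near 0 FPKM.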

Other observations

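The tests of libraries 5 and 6, of relative depth, of the correlations within each label spelling and of the level that admixture would bring were chosen after the data were examined, and the 3 patterns weighed below were themselves noticed in a first look at the same data, so they are hypotheses. What each explanation would show was written down after that look and before the deciding value was computed, with the relative depth of each library already seen, except for the level that admixture would bring, where values of some of the genes had been seen. Some outcomes are not read below as was written. By what was written, scaling would explain the split in direction and T-cell libraries 5 and 6 the wider spread. Chance would also have been excluded for sex. Each of these is left undecided below, for the reason given there. Dixon's gap singled out no T-cell library in any of 16 measures, where chance singles out 1 in 20. The IDs given individually entered this test as FPKM, not as log2(FPKM + 1), and the result for them holds on that scale only. On a log scale a low library can stand farther apart, and that was not tested. For ENSCAFG00000000990, T-cell library 6 stood at 2.85 FPKM and the next lowest T-cell library at 127.4 FPKM. Dixon's test takes 1 library at a time, so a pair of distant libraries can hide each other. Libraries 5 and 6 were chosen from the component plot and their correlations.

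The mean log2(FPKM + 1) of the class genes varied within each phenotype, and on this scale it varied in opposite sets. Among B-cell tumours the mean log2(FPKM + 1) of the 813 genes at least 2-fold higher in T-cell tumours (T-higher genes) ran from 1.86 to 3.15 (SD 0.362, n = 20), while that of the 418 genes at least 2-fold higher in B-cell tumours ran only from 4.82 to 5.31 (SD 0.152). Among T-cell tumours the genes higher in B-cell tumours ran from 3.03 to 4.22 (SD 0.478, n = 9), and the genes higher in T-cell tumours from 3.73 to 4.21 (SD 0.160). The shares of all FPKM did not show this pattern. T-higher genes had an SD of 0.653% over B-cell and 1.155% over T-cell libraries. The genes higher in B-cell tumours had 1.84% and 1.89%. Both sets were chosen on these same libraries. Over the 9 T-cell libraries the 2 mean log2 levels correlated at a Pearson r of -0.309 (exact permutation p = 0.415, adjusted 0.498; Spearman rho -0.317, p = 0.41), and at -0.752 without the 2 libraries farthest from the median. The number of genes at 0 in a B-cell library correlated with log2 relative depth at -0.643 (n = 20, permutation p = 0.00212, adjusted 0.00636; Spearman rho -0.602, p = 0.0067), and at -0.499 without 2 libraries. The T-cell libraries also fell into sets by correlation. Libraries 1, 2, 3 and 7 correlated at 0.931 to 0.968 and libraries 4, 8 and 9 at 0.929 to 0.932, against 0.852 to 0.918 between these sets. Library 5 correlated with the others at 0.714 to 0.863 and library 6 at 0.714 to 0.823. The level of the genes higher in B-cell tumours was 4.02 to 4.22 in libraries 1, 2, 3 and 7, 3.03 to 3.60 in libraries 4, 8 and 9, and 3.18 and 3.20 in libraries 6 and 5. These sets were picked from the same data, so this difference was not tested.

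The T-higher genes varied between B-cell tumours, and a candidate explanation is admixture of RNA with the profile of the T-cell tumours, which should lower the genes higher in B-cell tumours in the same libraries. The 2 levels correlated at a Pearson r of -0.686 over the 20 B-cell libraries (permutation p = 0.00126, adjusted 0.00636 over 6 relations; Spearman rho -0.577, p = 0.00814; r -0.646 without the 2 libraries farthest from the median), at -0.743 where the label has a space (n = 12, permutation p = 0.00726) and at -0.591 where it has a hyphen (n = 8, exact permutation p = 0.129), which fell to -0.17 without 2 libraries and was not shown there on its own. ENSCAFG00000007379 went both ways: against the level that admixture as the whole difference would bring, taken from the lowest T-cell library, it was at or above it in 3 of 18 B-cell libraries (6.27 against 5.78 FPKM in library 17) and below 0.5 of it in 11 (0.255 against 13.7 FPKM in library 8, whose 3.41% was the highest share of FPKM in T-higher genes), and 1 gene excludes nothing. Over all T-higher genes with such a need of at least 1 FPKM, a median of 0.814% per library lay below 0.5 of it in 18 B-cell libraries, but B-cell library 5, with the lowest share, gave a median of only 3.0% for the same needs, so that test decides nothing. Unequal depth is argued against, as the level of the T-higher genes correlated with log2 relative depth at -0.127 (permutation p = 0.593, adjusted 0.593; Spearman rho -0.174), while a difference between the tumour cells themselves and the relative nature of FPKM stay open and untested.

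Expression varied more between T-cell tumours, with a ratio of the mean SD per gene of 1.29. Low FPKM is argued against, with a ratio of 1.31 over genes with a mean FPKM of at least 5, and unequal depth too, with 1.22 after log2 relative depth was regressed out within each phenotype. Group size does not account for it, since 100 draws of 9 B-cell libraries gave mean SDs of 0.368 to 0.514 against 0.592. Without T-cell libraries 5 and 6 the ratio was 0.997, but these are the farthest from the T-cell mean and their removal lowers it by construction, so their part cannot be told apart from a wider spread of all T-cell tumours; leaving out the 2 farthest of each phenotype (also B-cell 5 and 8) gave 1.10. T-cell library 5 also had the lowest relative depth, at 0.522, but library 6 stood at 1.62, and different kinds of T-cell lymphoma stay open as an untested explanation.

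More genes were higher than lower in T-cell tumours as deposited, 58.5% of those called. Median-of-ratios scaling gave 48.9% and quantile normalization 45.5%. Both centre the libraries on each other, which takes out a shift shared by most genes whether it is real or not. Scaling therefore cannot be told apart from a real excess. With both scalings the split passed even, so its direction is not settled either. A difference in depth is argued against, with 58.2% after log2 relative depth was added as a covariate. Among genes at least 2-fold different the share fell from 66.0% to 58.4% and 55.2% with these scalings, and whether this is biological was not tested.

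Other splits of the 29 libraries bear on the counts of genes. For phenotype, 1 of 100 splits, the real one, gave 4664 genes, and the highest other gave 2, so chance can be excluded. For sex, permuted within phenotype, 3 of 100 splits gave as many as the 1 gene called, the real one included. The highest other gave 24. A count of 1 gene that random splits also reached or exceeded does not exclude chance. For neuter status and for the interaction the real count was 0, so all 100 splits give at least as many whatever the data, which says nothing about chance. Their highest other splits gave 475 and 1076 genes, and 14 and 37 splits gave any. Such numbers may reflect a structure of the samples or correlated genes that are called together, and neither was tested.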
